A study of Lotus japonicus with 9 samples.

How the data were processed

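RNA was measured in laser-captured tissue of Lotus japonicus root nodules on 9 single-colour arrays. Per the labels, plants of the MG-20 Miyakojima accession were inoculated with Mesorhizobium loti MAFF303099, the bacterium that fixes nitrogen inside the nodule. Per the labels' protocols, nodules were fixed in an ethanol and acetic acid mixture, embedded in paraffin and cut at 16 µm before laser microdissection, and the RNA was labelled with Cy3 after linear amplification. The labels give 3 arrays each for the infection zone, the parenchyma and the inner cortex, and the series' design text calls the arrays of a cell type independent experiments. The labels do not say whether the zones of one experiment came from the same plants or nodules. If arrays of the same zone shared a plant, p-values over arrays are too small. Plants shared between zones would be a pairing that the main fit leaves out. The p-values measure only the spread between these arrays.

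Per the file headers, each array carried 21495 non-control probes of 60 nt and 1417 control spots, and was read with Agilent Feature Extraction 10.5.1.1, which the submitters' processing notes also name. The deposited scanner files give the Cy3 intensity of each spot on a linear scale. Per the file headers, the processed signal used here had been background-subtracted and corrected for spatial and multiplicative trends, with surrogate values for dim spots, and had not been normalized between arrays. The authors also deposited a value table on a log2-like scale, whose preparation is not given in the sources used here. Set against the scanner signals, its slope on log2 signal was near 1, from 0.956 to 1.06 among bright probes. The quartiles were nearly equal in all 9 columns. The column medians were -1.94 for each of the 3 infection zone, 3 parenchyma and 3 inner cortex columns. The base of its logarithm and its centring remain unknown, and 21.7% to 52.8% of a column was blank.

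The value table and the scanner files do not carry the same labels for the parenchyma and inner cortex. The rank order of a column should equal that of its own array. For 4 of the 9 columns, all 3 of the infection zone and parenchyma 3, it did, with Spearman's rho rounding to 1. A further 4 columns had the rank order of an array with the other label, and 1 column, inner cortex 2, had that of none of the 9 arrays. Each scanner file was kept with the sample it was deposited for, and "parenchyma" and "inner cortex" below mean arrays with that label in the scanner files. Which label set is right is not settled by these data.

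Signals were taken to log2 and each array's 75th percentile over non-control probes was subtracted. Control spots were left out, 33 spots with an outlier flag were set to missing, and 0 spots were saturated. Over all arrays, 50.3% of the spots were well above background. A probe was tested when it was well above background on all 3 arrays of at least 1 zone, which left 10398 probes. The 3 zones were fitted together in limma 3.58.1 under R 4.3.3 with a shared spread and moderated statistics, and p-values were adjusted by the Benjamini-Hochberg method over the tested probes. A probe was called at an adjusted p below 0.05. A probe was enriched in a zone when both comparisons with the other zones were called and at least 2-fold. The main tests, the choice of samples and most alternatives were fixed before the data were examined. The 75th percentile over probes detected on all arrays, the random slide block, the zone labels of the value table and the fit without slide 2 were added after seeing the data. The comparison of the infection zone with the 6 other arrays was also added then, since it does not depend on which of them are parenchyma or inner cortex. Where a probe was not well above background on any array of the dimmer group, its fold is given as a lower bound. The bound sets the bright group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal of any probe well above background.

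The fits were tested on simulated data for 10380 probes, with the real means and spreads and 200 probes changed in 1 zone, over 20 simulations. For the infection zone against parenchyma, 3.6% of 2-fold, 43.6% of 4-fold, 66.5% of 8-fold and 88.8% of 32-fold changes were recovered. For the infection zone against inner cortex, these shares were 2.5%, 43.9%, 68.9% and 89.2%. For parenchyma against inner cortex, they were 3.7%, 42.5%, 69.8% and 90.3%. For the infection zone against all other arrays, they were 9.6%, 56.9%, 75.5% and 93.2%. False calls made up 5.11% to 5.59% of all calls in the 4 simulated comparisons. The simulated noise was independent for each probe and array. It lacked deviations shared by many probes of an array, differences in brightness and the floor of dim spots. The recovered and false shares may therefore not hold for the real arrays.

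The arrays came from 3 slides. Slide 1 held infection zone 1, infection zone 2 and parenchyma 1, slide 3 held infection zone 3 and parenchyma 3, and slide 2 held parenchyma 2 and all 3 inner cortex arrays. The infection zone and the inner cortex shared no slide. Alternatives covered the background correction (normexp with an offset of 50), the scaling, the filter on dim probes, the variance model, the samples in the fit, blocks for slide and replicate number, the authors' value table and leaving out each array. The offset is added to every signal, so normexp shrinks folds that reach down to signals well under 50. The authors' value table was fitted under its own zone labels, on 10897 probes. That alternative therefore changed both the values and the arrays counted as parenchyma and inner cortex.

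The scanner files describe every probe as unknown and give no map position, and the files do not pair identifiers with gene names. None of the identifiers was found in the gene table of the reference, which lists 40429 genes. The 38 gene lists fixed beforehand, among them the markers of infected cells, vascular and boundary tissues, matched 0 probes, so no list was tested. The rule for named genes asked for the called probes with a gene name and the largest folds, with no overlap between the 3 arrays of each group and with every array of the brighter group well above background. As no probe had a name, the rule was kept without that condition. At most 2 identifiers per direction are printed: the probe with the largest fitted fold of each infection zone comparison, or the next for parenchyma where both comparisons had the same probe. A fitted fold against a group below background is not exact, so this order ranks no such probe above another. Genome coordinates are not given here for the same reason.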

Results

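Transcripts were measured in 3 tissues of the nitrogen-fixing root nodule of Lotus japonicus, a model legume. The infection zone holds the cells colonised by the rhizobia, and the parenchyma and inner cortex are tissues around it. Each tissue was represented by 3 arrays, each from laser-captured sections. The arrays differed in brightness. The number of probes well above background ran from 6085 of 21495 on inner cortex 3, or 28.3%, to 12634 on parenchyma 1, or 58.8%. The 75th percentile of the signal was 12.8 on inner cortex 3 and 304 on infection zone 1. The number of arrays limits the precision of every comparison.

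The infection zone stood apart from the other tissues. Across the 5221 probes well above background on all 9 arrays, Pearson's r between 2 infection zone arrays was 0.749 to 0.869. Between the infection zone and parenchyma it was 0.416 to 0.710, and between the infection zone and inner cortex 0.556 to 0.754. Parenchyma and inner cortex arrays correlated at 0.807 to 0.982, which overlapped the ranges within parenchyma, 0.792 to 0.921, and within inner cortex, 0.869 to 0.917. These correlations are across probes, which are not independent replicates. All 3 infection zone arrays detected 8998 probes, and 128 of these were well above background on none of the 6 other arrays. The corresponding number was 1 of 8993 for parenchyma and 9 of 5846 for inner cortex, where inner cortex 3 limited detection.

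**Figure D1:**
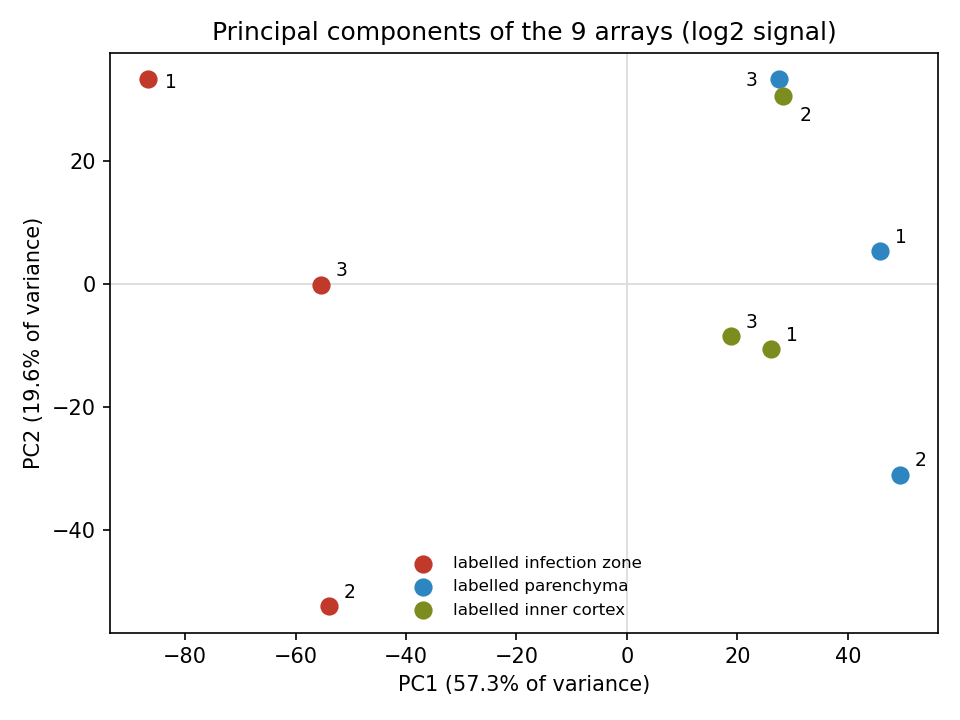
Scores of the 9 arrays on the first 2 principal components of log2 signal, with each point an array, numbered by replicate, and axes giving the share of variance. PC1 carried 57.3% of the variance and placed the 3 infection zone arrays between -86.7 and -53.9 and the 6 other arrays between 18.8 and 49.4.

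The first comparison asks which transcripts differ between the infection zone and the parenchyma. In the infection zone, 1202 probes were higher and 1393 lower, together 2595 of the 10398 tested (limma, adjusted p below 0.05). The median fold among called probes was 8.14 for those lower in the infection zone and 4.31 for those higher. It was 11.97 and 4.51 with median scaling, and 4.26 and 4.14 with normexp background correction, which left little difference between the directions. The offset of that correction shrinks folds that reach down to dim spots, so it does not settle whether the directions differ. The fitted fold was 8 or more for 395 higher and 706 lower probes, and 32 or more for 164 and 223. These counts include probes below background in the dimmer tissue, whose fitted folds are not exact. Of the higher probes, 173 were not well above background on any parenchyma array, and of the lower probes, 213 were not so on any infection zone array.

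Probe GA00933 was higher than in parenchyma, with the sequence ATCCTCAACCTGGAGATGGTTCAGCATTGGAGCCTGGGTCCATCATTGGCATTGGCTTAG. Its log2 signal relative to the 75th percentile was 8.33 ± 1.00 (SD, n = 3 arrays) in the infection zone, -0.24 ± 2.03 in parenchyma and 3.65 ± 1.39 in inner cortex. The log2 difference between infection zone and parenchyma was 8.57 ± 1.06 (SE; limma, adjusted p = 0.000786), and the probe was well above background on all 9 arrays. That difference was 7.67 without parenchyma 1, 9.67 without parenchyma 3 and 7.65 with normexp background correction. With the value table's zone labels the difference was 4.77 (limma, adjusted p = 0.0093). With the authors' table, which changes both values and zone labels, it was 4.63 (adjusted p = 0.031). Against inner cortex the difference was 4.68 ± 1.06 (limma, adjusted p = 0.0166). Probe GA03735 was among the lower ones, with the sequence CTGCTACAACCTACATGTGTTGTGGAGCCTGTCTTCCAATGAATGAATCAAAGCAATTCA. It stood at 3.16 ± 0.62 in parenchyma and was not well above background on any infection zone array, so it was at least 122-fold lower there on the processed signals (limma, adjusted p = 0.00056). With normexp background correction the fitted fold was 20.5, below that bound, with an adjusted p of 0.00331. Probe GB06893, with the sequence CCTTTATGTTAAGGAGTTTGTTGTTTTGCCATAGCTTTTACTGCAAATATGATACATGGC, stood at 4.63 ± 1.87 in parenchyma and -3.72 ± 2.84 in the infection zone. It was well above background on 2 of the 3 infection zone arrays. Its log2 difference was -8.36 ± 1.39 (SE; limma, adjusted p = 0.00297), or -5.73 with the table's labels (adjusted p = 0.018) and -5.17 in the authors' table (adjusted p = 0.0114). Without infection zone 1, the array not well above background, it was -6.72 (adjusted p = 0.00334), and with normexp background correction -5.57 (adjusted p = 0.00581).

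**Figure D2:**
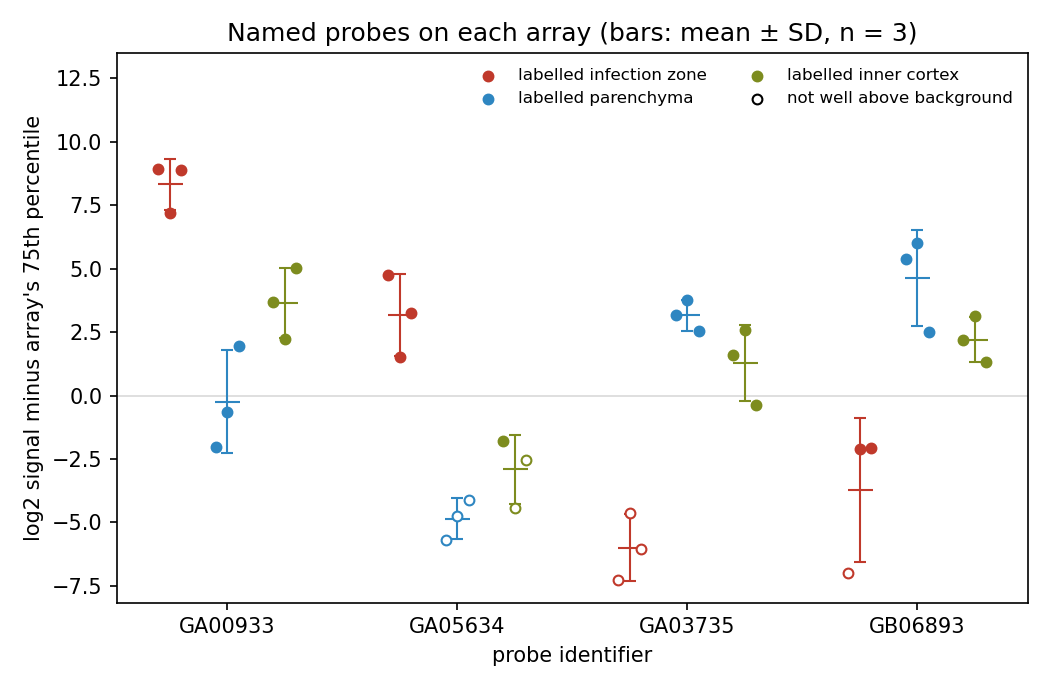
Log2 signal minus the array's 75th percentile for the 4 probes named in the text, by tissue label, with points for arrays, open points for spots not well above background, and bars for the mean ± SD of 3 arrays. GA00933 averaged 8.33 in the infection zone and -0.24 in parenchyma, and GA03735 was not well above background on any infection zone array.

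Slides 1 and 3 held both tissues, and the comparison could be made within each. The infection zone minus parenchyma folds of the 2 slides correlated at r = 0.811 across 10392 probes, and 78.6% of the probes had the same sign. With slide as a block 1676 probes were called, of which 1627 were among the 2595, and leaving out parenchyma 1 gave 1543. Normexp background correction called 1345 probes, the table of the authors, with its own zone labels, gave 580, and the probes well above background on all 9 arrays 1189. Scaling by the median in place of the 75th percentile called 2587 probes and moved the share of higher probes from 46.3% to 63.8%, while the median log2 difference of all probes moved from 0.16 to 0.62.

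The second comparison asks which transcripts differ between the infection zone and the inner cortex. Of the 10398 probes, 1015 were higher and 1251 lower in the infection zone, 2266 in all or 21.8% (limma, adjusted p below 0.05). The median fold was 3.67 for the higher and 7.55 for the lower probes. With median scaling it was 3.69 and 7.08. With normexp background correction, whose offset shrinks folds of dim spots, the order turned, to 4.55 and 4.20. The fitted fold was 8 or more for 215 higher and 599 lower probes, and 32 or more for 13 and 95. Probes below background in the dimmer tissue, whose fitted folds are not exact, are among them. Relative to the 75th percentile, spots not well above background had medians of -3.71, -5.09 and -2.46 on inner cortex 1, 2 and 3. On infection zone 1, 2 and 3 these medians were -6.86, -4.44 and -5.63. The high floor of inner cortex 3 leaves less room for large folds toward the infection zone. The counts of the 2 directions are therefore not on an equal footing. On no inner cortex array were 82 of the higher probes well above background, and on no infection zone array 219 of the lower ones.

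Probe GA05634, with the sequence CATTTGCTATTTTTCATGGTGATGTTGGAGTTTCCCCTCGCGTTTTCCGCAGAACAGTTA, was higher than in inner cortex. Its log2 signal relative to the 75th percentile was 3.18 ± 1.62 (SD, n = 3 arrays) in the infection zone and -2.91 ± 1.37 in inner cortex, where 1 of 3 arrays had it well above background. The fitted log2 difference was 6.09 ± 0.91 (SE; limma, adjusted p = 0.00361), and is not exact because it rests in part on signals near background. It was 3.37 with normexp background correction (adjusted p = 0.0309), 5.30 without infection zone 1 and 6.92 without infection zone 2. With the value table's labels the probe was also higher (adjusted p = 0.00137), with no fold given, since neither array then in the inner cortex group had it well above background. GA03735 was lower here too. It stood at 1.27 ± 1.49 in inner cortex and was at least 32.8-fold lower in the infection zone on the processed signals (limma, adjusted p = 0.00221). With normexp background correction the fitted fold was 6.81, with an adjusted p of 0.0381 (limma). The offset lowers this fold too, so it does not contradict the bound.

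The slide limits this comparison, since the infection zone and inner cortex shared none. With slide as a fixed block, where only parenchyma arrays link the slides, limma called 0 probes, and 1869 had an unadjusted p below 0.05. The median SE of a probe rose from 0.449 to 0.790 on the log2 scale under the block. At GA05634 the log2 difference was then 6.35 ± 1.84 (SE), with an adjusted p of 0.171, and at GA00933 4.45 ± 1.72, with an adjusted p of 0.249. At GA03735 the fitted difference went from -7.26 ± 0.85 to -6.41 ± 1.71, with an adjusted p of 0.168. Neither fitted value of GA03735 is a bound. At GB06893 the difference went from -5.93 ± 1.39, with an adjusted p of 0.0184, to -3.85 ± 2.74, with an adjusted p of 0.493. The standard errors of these 4 probes rose under the block, and their folds changed by different amounts. Median scaling called 4027 probes and moved the share of higher probes from 44.8% to 82.3%, and the median log2 difference of all probes from 0.12 to 1.01. Normexp background correction called 699 probes, the fit of only these zones 1285, and the authors' table, with its own zone labels, gave 1059 probes. Leaving out inner cortex 1 gave 1192 probes, and leaving out inner cortex 2 gave 1265.

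The calls of the first and second comparisons overlapped. There were 793 probes higher in the infection zone in both and 1094 lower in both, and 0 called in opposite directions. Independent lists of the same sizes would share 117 and 168 probes. Both comparisons use the same infection zone arrays, and part of the excess may come from that. Across all tested probes the log2 differences of both comparisons correlated at r = 0.936, against 0.50 in simulated unchanged groups that share arrays in the same way. Their covariance was 2.95, against 0.229 in the simulation. The simulated noise was independent between probes, so neither simulated value allows for deviations that many probes of a real array share. Infection zone enriched probes, at least 2-fold higher than in both other tissues, numbered 767, and 1084 probes were at least 2-fold lower than in both. The enriched count fell to 485 without parenchyma 1, 420 without inner cortex 1 and 426 without inner cortex 2. It was 1513 with median scaling, 393 with normexp background correction and 407 without the filter on dim probes. On probes well above background on all 9 arrays it was 355, and from the authors' table, with its own zone labels, 136. With slide as a fixed block it was 0, since no probe was then called against inner cortex, and no shared call remained.

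The third comparison asks which transcripts differ between the parenchyma and the inner cortex. No probe was called by limma, with the smallest adjusted p at 0.267. At an unadjusted p below 0.05 there were 573 probes, where 520 of 10398 would be expected by chance. That number depended on single arrays: it was 243, 368 and 987 without parenchyma 1, 2 and 3, and 320, 890 and 235 without inner cortex 1, 2 and 3. In the authors' table, with its own zone labels, it was 1459 of 10897. Parenchyma enriched and inner cortex enriched probes both numbered 0. On simulated data with independent noise, the fit recovered 42.5% of 4-fold and 69.8% of 8-fold changes for this comparison. Differences of 2-fold, recovered in 3.7%, were largely out of reach, and recovery on the real arrays may differ. Across the 3 tissues, the moderated F test of limma called 2237 probes, and 1443 without parenchyma 1. It called 853 from the authors' table with its own zone labels, and 923 with normexp background correction. Among the probes well above background on all 9 arrays it called 978, and with slide as a fixed block 1034.

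The labels of parenchyma and inner cortex are in conflict between the authors' deposited files, which bears on the 3 pairwise comparisons. The value table's column parenchyma 1 had the rank order of the array inner cortex 1, and parenchyma 2 that of inner cortex 3. Its column inner cortex 1 had the rank order of the array parenchyma 1, and inner cortex 3 that of parenchyma 2. The column inner cortex 2 was closest to the array parenchyma 1, at Spearman's rho = 0.955, and reached 0.912 with its own array. With the table's labels, and the array inner cortex 2 left out, the infection zone differed from parenchyma at 1965 probes and from inner cortex at 2080. Parenchyma and inner cortex then differed at 0 probes by limma, with 940 at an unadjusted p below 0.05.

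**Figure D3:**
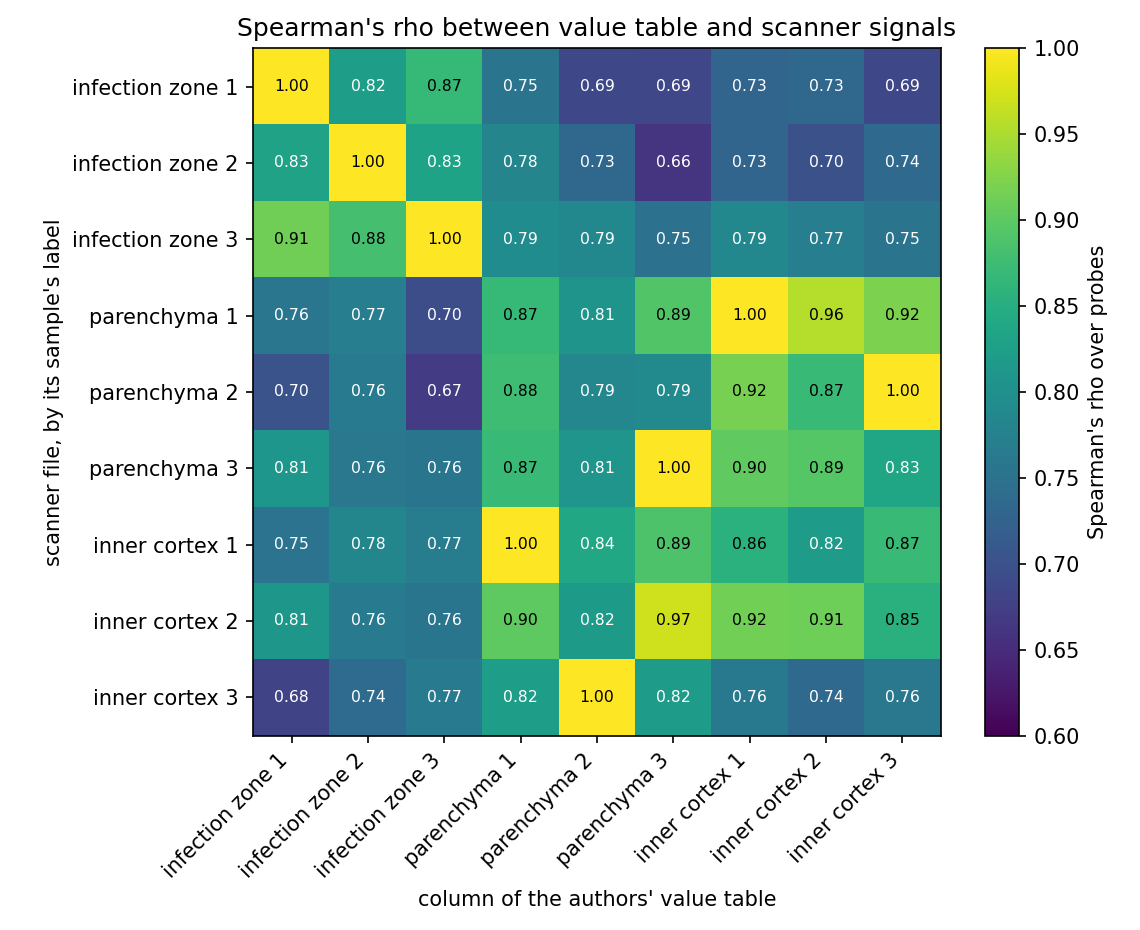
Spearman's rho over probes between each column of the authors' value table and the signal of each scanner file, both named by the labels of their samples. The infection zone and parenchyma 3 match on the diagonal at 1.00, while 4 columns of parenchyma and inner cortex reach 1.00 with an array of the other label.

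The infection zone keeps its label in both sources, so it was also compared with the 6 other arrays together. In that comparison 1620 probes were higher and 1689 lower in the infection zone, 3309 of 10398 or 31.8% (limma, adjusted p below 0.05), with median folds of 2.98 and 6.06, or 2.62 and 2.83 with normexp background correction. The share of higher probes, 49.0%, was 77.0% with median scaling, with 3343 higher and 1000 lower, and 32.6% without the filter on dim probes, with 873 higher and 1803 lower. At GA00933 the log2 difference was 6.62 ± 1.39 (SE; limma, adjusted p = 0.00617). GA05634 was higher with an adjusted p of 0.000666, and is given no fold because 5 of the 6 other arrays did not have it well above background. At GB06893 it was -7.14 ± 1.33 (adjusted p = 0.0036), and GA03735, not well above background on any infection zone array, was lower with an adjusted p of 0.000313. The array inner cortex 2, which matched no column of the authors' table, is among the 6, and without it 2787 probes were called. Normexp background correction called 2080 probes, and the probes well above background on all 9 arrays gave 1600. The table of the authors, whose column inner cortex 2 matched none of the 9 arrays, gave 990. With slide as a block the count was 1635, and without slide 2 it was 1237, in a fit of 5 arrays.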

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

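The comparison of the infection zone with all other arrays, the 75th percentile over detected probes, the random slide block, the table's labels and the fit without slide 2 were chosen after seeing the data. Normexp background correction called 1345 probes between infection zone and parenchyma, 699 against inner cortex (64.2% higher, from 44.8%), 2080 against all other arrays, 923 by the F test and 393 infection zone enriched. Median scaling gave 4027 probes against inner cortex (82.3% higher) and 1513 enriched, and the share higher was 63.8% against parenchyma and 77.0% against all others, from 49.0%. Without the filter on dim probes 407 were enriched, and the shares higher were 36.0%, 19.8% and 32.6% against parenchyma, inner cortex and all others. Probes well above background on all 9 arrays gave 1189, 1022, 1600 against all others, 978 by F and 355 enriched, from 5221 tested. Slide as a fixed block gave 1676, 0, 1635, 1034 by F and 0 enriched. The authors' value table, with its own zone labels, gave 580, 1059 (26.3% higher), 990 (31.8% higher), 853 by F and 136 enriched. Fitting only the 2 groups gave 1285 against inner cortex, and the fit without slide 2 gave 1237 against all others. Except for the smaller set of probes or arrays, the cause was not tested. Leaving out 1 array gave 1543 to 2478 probes against parenchyma, 1192 to 2240 against inner cortex, 2519 to 3322 against all others, 1443 to 2096 by F and 420 to 775 enriched. Parenchyma against inner cortex gave 0 calls in all 23 alternatives, with 160 to 1706 probes at an unadjusted p below 0.05. In the comparisons by which the 4 probes were named, 101 of 103 alternative values kept their direction and call. The other 2, GA05634 and GA03735 against inner cortex under the fixed slide block, kept their direction. The calls of GA00933 and GB06893 against inner cortex, outside those values, were lost there too. Settings in which a probe was not tested are not among the 103. These were the probes well above background on all 9 arrays for GA03735, GA05634 and GB06893, and the authors' table for GA03735 and GA05634.

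The replicate number did not pair the arrays: same-numbered arrays of different zones correlated at -0.500 to 0.473 in their deviations, with 2 of 9 pairs above 0.1. Of the differently numbered pairs, 7 of 18 were above 0.1. Infection zone 1, parenchyma 3 and inner cortex 2 correlated at 0.363 to 0.414 with one another. Infection zone 2, parenchyma 2 and inner cortex 1 did so at 0.375 to 0.473. Whether the zones are paired under other numbers was not tested. With the number as a block, the replicate block fit called 2186 probes against parenchyma, 1789 against inner cortex, 0 between parenchyma and inner cortex, 2908 against all others, 1698 by F and 600 enriched, with 0 parenchyma and 0 inner cortex enriched. The gene list tests gave no value under any setting, since no probe had a name. Signal over background limits inner cortex most, where 1 array had 28.3% of its probes well above background.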

Other observations

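The tests of array brightness and probe GC content for the infection zone, of the slide for its comparison with inner cortex, and of the splits that involve the infection zone were set before their results were seen. All other tests here were chosen after the pattern or the value had been seen: the slide test against parenchyma, the tests of the labels and of the shared axis, and the splits for parenchyma against inner cortex and for the parenchyma and inner cortex enriched counts.

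Transcripts of the infection zone were also detected on arrays of the other tissues, on some arrays more than on others. For each of the 6 other arrays, the 100 probes with the largest excess in the infection zone over the remaining 5 arrays were taken. Their median log2 signal relative to the infection zone was -8.24, -7.26 and -5.88 on parenchyma 1, 2 and 3, and -4.06, -5.51 and -3.51 on inner cortex 1, 2 and 3. Of the 100 probes, 38, 31 and 58 were well above background on the parenchyma arrays and 83, 75 and 64 on the inner cortex arrays. The medians are not levels of expression alone: where few probes are above background they lie near the floor, and the median of spots not well above background ran from -5.54 on parenchyma 1 to -2.46 on inner cortex 3 relative to the 75th percentile. Array brightness may therefore set part of the difference in medians, which was not tested. The exact permutation test of the medians between these labels gave p = 0.1 (two-sided), the smallest that 3 arrays against 3 allow. The array parenchyma 3 correlated with inner cortex 2 at r = 0.982, above every pair within a zone.

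The infection zone arrays differed from the others at 3309 probes, and slide, array brightness and probe GC content were tested as explanations. A slide effect against parenchyma would leave the folds of slides 1 and 3 unrelated, and they correlated at r = 0.811. Against inner cortex, a slide 2 effect would place parenchyma 1 and 3, on other slides, with the infection zone. At the 2266 called probes they covered at most a median share of -0.0535 of the difference. Those calls rest on a spread that includes parenchyma, with parenchyma 2 on slide 2 and parenchyma 1 and 3 off it. Probes with a slide 2 effect were therefore less likely to be called, and the share speaks only for called probes. With slide as a fixed block, limma called 0 probes against inner cortex. The prediction for array brightness was as many calls between the 3 brightest arrays and the rest, and that gave 0 against 3309. Those arrays were infection zone 1, inner cortex 2 and parenchyma 1, so both sides mixed the zones. Every split other than the real one gave at most 1 call, so this result cannot decide on brightness. Removing each array's trend on probe GC content left 3286 calls. A difference between the tissues remains a hypothesis that these values allow. Array brightness and, against inner cortex, the slide stay open, and shared plants and the capture itself stay untested.

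Other splits of the arrays bear on the same counts. Of the 84 splits into 3 and 6 arrays, 1, the real one, gave as many calls, and the highest of the others gave 1 against 3309. A share of 1 in 84 is the smallest possible, and this comparison was chosen after seeing the data. Every other split grouped infection zone arrays with arrays of other tissues. Chance is therefore made less likely but not excluded. Of 100 drawn splits into 3, 3 and 3, 2 reached the F test's 2237 probes, the highest other being 2360. In all 5 drawn splits with over 1 probe, the infection zone arrays were together, which points to a structure of the samples in which that zone stands apart, however the other 6 are grouped. For the infection zone enriched count of 767, 1 of the 100 splits gave as many, with 0 as the highest other. Zone names were drawn at random in the other splits, and infection zone arrays that stayed together there bore another zone's name. Under such a name up to 770 probes were enriched, so the 0 follows from the naming and does not test the count. For the parenchyma and inner cortex enriched counts of 0, all 100 splits gave as many, which is fixed in advance for a count of 0 and tests nothing. The highest others, 731 and 770 probes, arose where the 3 infection zone arrays bore that label. The 3 pairwise counts, 2595, 2266 and 0, have 10 splits each, too few for a share under 0.05. As many calls were given by 1, 1 and 10 of them, and the highest other was 0 in each.

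The authors' value table and the scanner files disagree on which arrays are parenchyma and which inner cortex. A mere difference in normalization between them would keep the rank order, and 5 columns fell under 0.99 with their own scanner file, 4 of them matching another array. Whether the scanner files carry the wrong zone label cannot be told apart from an error in the table. The median signals of infection zone probes, which may depend on array brightness, separated the zones under the scanner labels, by a gap of 0.37 in log2. In the table's columns they overlapped, where the gap from parenchyma to inner cortex was -0.40. That overlap rested on the column inner cortex 2, which matched no array, at -6.37 against -6.76 for parenchyma 3. The columns inner cortex 1 and 3, at -7.23 and -7.09, lay below every parenchyma column. On the scanner signals the table's labels also separated the zones, in the opposite direction. Arrays it labels parenchyma stood at -5.88, -4.06 and -3.51, and those it labels inner cortex at -8.24 and -7.26. The gaps of 0.37 and -0.40 met the bound first set against wrong scanner labels. That bound was tightened to an exact p below 0.05 after these values were seen, and 3 arrays against 3 cannot reach it, so the test decides nothing, and no biological explanation was tested.

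Within zones, infection zone 1, parenchyma 3 and inner cortex 2 deviated together against infection zone 2, parenchyma 2 and inner cortex 1 and 3. The axis of these deviations held 45.6% of the within-zone variance, and inner cortex 1 and 3 scored -18.1 and -20.3 on it. A slide effect would cancel between arrays of a slide, yet the same-slide differences infection zone 1 minus 2 and inner cortex 2 minus 1 correlated at r = 0.467 across probes. That correlation is part of the pattern that prompted it, with inner cortex 1 taken rather than inner cortex 3, so it is not independent support. Probe GC content was unrelated to the axis, with Spearman's rho = -0.00526. Array brightness may contribute and stays open. Over the 9 arrays, with both measures centred within zones, Pearson's r was 0.622 (exact permutation p = 0.0972) and Spearman's rho 0.550 (exact permutation p = 0.171), from 216 permutations within zones. Without inner cortex 2 and inner cortex 3, the 2 arrays farthest from the median of the centred brightness, r was 0.683. The labels name no factor for this axis, and they leave open whether zones shared plants. Whether the axis follows such sharing was not tested, and no biological explanation was tested.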
